A study of Caenorhabditis elegans with 2 samples.

How the data were processed

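Chromatin immunoprecipitation with sequencing was made, per the labels, from whole L1 larvae of 1 transgenic strain at 6 hours, in 2 biological replicates with 1 technical replicate each. The labels name anti-GFP for the precipitation in the description and ets-5 in the antibody tag. Fragmentation was by sonication and the genome build ce11, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. Since the reads were not used, depth is unknown and no interval that needs it is given. The intervals given for shares of regions are exact 95% binomial intervals.

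The deposited values are region lists, 4 ranked and 4 that pass a threshold on the irreproducible discovery rate (IDR), which measures how well a region's rank recurs between 2 lists. The deposited score is a whole number equal to 125 times the −log2 of the global IDR, at most 1000, which was checked on the ranked lists. The deposited signal is the value given to each region by the authors' caller, on a scale that is not stated, and it was used only to rank or describe regions within a list. The deposited ranked lists also hold the −log10 of the local and of the global IDR for each region. Per the text deposited with the samples, the lists were made from the alignments and 1 further file that is also behind the fold-over-control tracks, and the lists that pass the threshold used 1 more file, whose role is not stated. The lowest score in a list passing the threshold was 830, which corresponds to a global IDR of 0.01.

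The lists' contents were checked against each other. All 250 regions of the main list were found with the same position and score in a ranked list of 126002 regions, and all 177 of the conservative list in another of 123697 regions. In the latter, 87.9% of the first signal column occurred in the ranked list of replicate 1 and 78.5% of the second in that of replicate 2, so it compares the replicates. The corresponding 2 signal columns of the former could not be matched to a sample and were not used, and how its compared lists were drawn is not given in the sources used here. The main and the conservative list shared 145 regions by overlap. The ranked lists of the replicates held 108309 (replicate 1) and 92443 (replicate 2) regions. The lists passing the threshold covered 75829 bp (main), 53803 bp (conservative), 6384 bp (replicate 1) and 7245 bp (replicate 2), and the 250 main regions merged into 236 that do not overlap. The count was 1.24 times higher in the longer replicate list than in the shorter, and 1.41 times higher in the main than in the conservative list.

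Regions were placed on the Ensembl release 115 annotation, whose coordinates are those of ce11, with 19973 protein-coding genes. Coordinates are 1-based. A promoter was within 500 bp of an annotated start site of a protein-coding gene. Words were searched within 100 bp of the summit on both strands, gene lists within 1000 bp of a start site, and noncoding genes within 500 bp of the gene body. The background was the 125671 regions of the ranked list behind the main list that did not pass and overlap no passing region. A second background of 4993 regions was matched on GC content within 2 points and on promoter position, at up to 20 for each main region. Shares were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 23 gene lists, 5 noncoding gene types, 6 chromosomes, 5 location classes or 2080 words. Mean GC content and median signal were tested with permutation tests of 100000 resamples. Centring of the ETS word compared 50 bp on each side of the summit with flanks 150 to 200 bp away, by an exact sign test. The ets-5 locus was set against 10000 random windows on X. Windows near ets-5 were excluded from these draws, a choice made after the data were examined.

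The gene lists cover BAG neuron genes, pan-neuronal, serotonergic and ciliated neuron genes, neuropeptides, guanylyl cyclases, ETS-domain, ceh homeobox and nuclear receptor genes, cytosolic and mitochondrial ribosome, translation factors, proteasome, spliceosome, respiratory chain, vacuolar ATPase, chaperones, histones, cuticle collagens, and muscle, intestine, germline and hypodermis markers. A list member, opt-2, was not found in the annotation under that name. Only 4 lists passed in the main list, and 5 had an unadjusted p under 0.05.

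The tests, lists, backgrounds and windows, and most alternatives, were fixed before the data were examined. Named regions follow a rule fixed then too: the 25 main regions with the highest signal, the 5 highest in each replicate's own list, each BAG gene with its best region, and up to 4 members by signal of each list that has main regions. The remaining ribosomal regions, the regions around ets-5 and those at small nuclear RNA genes were named outside that rule, after their values were seen. So were the other dense stretches, the omitted region of highest signal and the members named from the test of lists over the whole ranked list. Alternatives included the conservative list, the 125 main regions of highest signal, each replicate alone, random genomic positions (20000) or the matched regions as background, other windows and ETS words, a stricter IDR, and other overlaps. A replicate was left out by testing the other replicate's own list against its own ranked list.

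The tests of the ETS share, words, gene lists, centring and GC content were tested on simulated data, with known changes planted among background regions. The promoter, noncoding gene, chromosome and location tests use the same Fisher's exact test and were not simulated separately, nor were the permutation tests of signal and the random windows on X. The ETS share test called 1 of 100 draws with nothing planted, 66 of 100 with 5% of 250 regions given the word and 100 of 100 with 10%. The word test, with only 1 draw per setting, called 0 of 2080 words with nothing planted and 3, with CCGGAA first, at 20%. A single draw does not measure how often it calls words falsely. The gene list test called the planted ribosomal list in 0, 43 and 100 of 100 draws at 0, 3 and 8 regions moved. The centring test called 1 and 100 of 100 draws at 0% and 20%, and the GC test 1 and 20 of 20 draws at 0 and 2 points added. The test of lists over the whole ranked list, simulated after it had been used, called 6, 47 and 98 of 100 random lists of 40 genes at an unadjusted p under 0.05 when 0, 5 and 10 units of signal were added.

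Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The ranked list behind the main list held 299 regions at a global IDR of 0.01 or less, of which 49 are not in the main list. They were left out of the comparisons because the authors' list leaves them out, and are described after the report.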

Results

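ETS-5 is an ETS-domain transcription factor of the nematode Caenorhabditis elegans, best known for its part in setting the identity of the BAG neurons, which sense oxygen and carbon dioxide. Its position on chromatin was profiled by ChIP-seq in whole larvae of the first stage (L1), hatched without food and collected at 6 hours. The worms carried a fosmid transgene, a large piece of genomic DNA, in which ets-5 is fused to a green fluorescent protein, and the fusion was precipitated with an antibody to that protein. The series holds 1 group with 2 biological replicates, so no condition is compared with another. The question addressed is where in the genome, and near which genes, the tagged protein gave signal that passed the authors' threshold. The main list holds 250 regions, the conservative list 177, and the replicates' own lists 21 (replicate 1) and 26 (replicate 2). The main and the conservative list have the same lowest score, 830, but come from different ranked lists. The conservative list, drawn from the ranked list that compares the replicates, is therefore not a tighter cut of the main list. Read depth is unknown from the files used here, and an input or untagged control was not analysed here. The control for each comparison is instead a background of 125671 ranked regions that did not pass the authors' threshold and overlap no passing region.

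The region with the highest signal in the main list lay at the promoter of rpl-3, which encodes a protein of the large ribosomal subunit (chromosome III:3867516-3867600 in ce11, 283 bp from the transcription start site). Its signal was 252 in the main list, 101 in replicate 1 and 154 in replicate 2. The signal is the authors' value for each region, whose scale is not stated, so it is used only to order regions within a list. A region between Y17G9B.5 and rpl-20 followed among promoters (IV:4749908-4750217, signal 177, at 177 bp and 285 bp from the 2 start sites). Further promoter regions among the 25 highest belonged to K08F11.1 (172), to F44E5.4 and F44E5.5, a pair of genes for inducible HSP70 chaperones (151), to atp-1, the alpha subunit of the mitochondrial ATP synthase, with mcrs-1 (147), and to cdc-48.1, an AAA ATPase that extracts ubiquitylated proteins (145). The list went on with pqn-51 and K11D12.14 (134), ets-5 itself (128), the RNA helicase gene mog-4 (124), the ubiquitin ligase gene eel-1 (124) and rpl-15 with K11H12.8 (121). In all, 11 of these 25 regions had their summit in a promoter, taken as within 500 bp of the start site of a protein-coding gene.

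The other regions of the 25 lay inside genes or between them. Introns held the regions in cmk-1, a calcium/calmodulin-dependent kinase gene (IV:1831225-1831534, signal 172), in stim-1, the calcium sensor of the endoplasmic reticulum (III:415366-415675, signal 139), and in Y41G9A.17 (125). Coding exons held those in dos-3 (III:835768-836077, signal 128) and in clc-7, a claudin-like gene (X:5073975-5074284, signal 122). Regions near ftt-2, a phosphoserine-binding adaptor gene (129, at 568 bp), and saeg-1 (128, at 900 bp) lay just outside promoters. The remaining regions were intergenic, with nearest genes duo-3 (I:10462594-10462903, signal 193, at 5730 bp), W02H3.3 (169.6), F40E3.3 at 1152 bp, the calmodulin gene cmd-1 (146, at 4791 bp), K02D3.1 (132), F20B6.9 (124) and F22H10.2 (119.9). The duo-3 region led the list of replicate 1 with a signal of 179, and no region of the ranked list of replicate 2 overlapped it. In replicate 1 it was followed by rpl-3, F44E5.4, K08F11.1 (94.9) and dos-3 (94.3). In replicate 2 the order was rpl-3, Y17G9B.5 with rpl-20 (94.0), a region 1187 bp from ets-5 (93.6), F40E3.3 (83.7) and pqn-51 (82.7).

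Regions of the main list lay close to transcription start sites more often than the background did. Of the 250 regions, 88 were in promoters, 35.2% (exact 95% binomial interval 29.3% to 41.5%), against 23.8% of the background, a ratio of 1.48 (Fisher's exact test, two-sided, p = 5.36e-05). Coding exons held 53 regions (21.2% against 23.5%), introns 46 (18.4% against 24.0%), untranslated exons 2 and intergenic sequence 61 (24.4% against 26.2%). None of these 4 classes differed from the background after adjustment over the 5 classes, the lowest of their adjusted p being 0.0947 for introns. The median distance to a start site was 991.5 bp in the main list and 1264 bp in the background. Within the list, promoter regions had a median signal of 84.8 and the others 83.5 (two-sided permutation test, p = 0.492). In replicate 1 alone the promoter share was 7 of 21 regions, 33.3%, which did not pass (ratio 1.40, Fisher's exact test, p = 0.308), while in replicate 2 alone it was 11 of 26, 42.3% (ratio 1.77, p = 0.0369). The intervals cover counting error only, and neighbouring regions are not independent of each other.

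The ETS core word CCGGAA, the textbook centre of ETS-domain binding sites, was about as frequent in the main list as in the background. It lay within 100 bp of the summit in 25 of 250 regions, 10% (interval 6.58% to 14.4%), against 9.19% (ratio 1.09, Fisher's exact test, two-sided, p = 0.660). In promoters it was found in 9 of 88 regions, 10.2%, against 8.47% (Fisher's exact test, p = 0.562). Among the 25 regions of highest signal it was present in 4, at F40E3.3, ftt-2, dos-3 and ets-5. It was absent from all 8 regions at ribosomal protein genes, which at a share of 10% does not set them apart. Regions with the word had a median signal of 80.9 and those without it 84.2 (two-sided permutation test, p = 0.264). The word lay more often within 50 bp of the summit than in flanks of equal length in 12 regions and less often in 8 (exact sign test, two-sided, p = 0.503). On simulated data the share test called the word in 66 of 100 draws when 5% of the regions were given it, and in 100 of 100 draws at 10%. The direction turned against the background matched on GC content and promoter position (10.6%, ratio 0.944, Fisher's exact test, p = 0.833) and for the shorter core GGAA, which was less frequent in the main list (82.0% against 87.9%, Fisher's exact test, p = 0.00639).

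**Figure D1:**
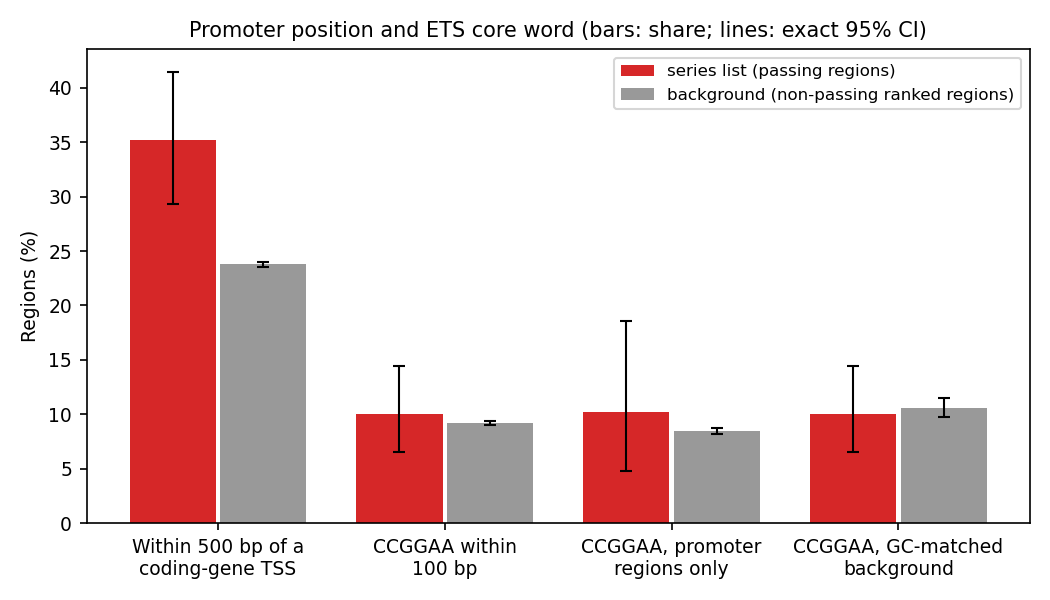
Percent of regions (vertical axis, starting at 0) with a summit within 500 bp of the transcription start site of a protein-coding gene, or with CCGGAA within 100 bp of the summit, for the 250 regions of the main list (red) and their backgrounds (grey); lines are exact 95% binomial intervals, and the last pair uses the background matched on GC content and promoter position. The promoter share was 35.2% against 23.8%, and the CCGGAA share lay near 10% in all 3 comparisons.

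Sequence around the summits was richer in G and C than the background. The mean GC content within 100 bp of the summit was 45.6% ± 7.58 (SD, 250 regions) against 38.3% ± 6.91 (SD, 125671 regions), 7.32 points higher (two-sided permutation test, p = 1e-05, the smallest value that 100000 resamples can give). Of 2080 six-base words, with reverse complements merged, 171 were more and 140 less frequent in the main list at a Benjamini-Hochberg adjusted p under 0.05. The leading words were AAAAAA, less frequent (30% against 53.1%), and CGCGCA (14% against 3.14%) and GCGCGC (9.2% against 1.53%), more frequent. CCGGAA ranked 1639 among the words (Fisher's exact test, adjusted p = 0.838). Against the background matched on GC content and promoter position, 6 words were more and 2 less frequent: CGCGCA (14% against 4.35%, Fisher's exact test, adjusted p = 1.15e-05), ACGCAA (15.6% against 6.33%), GCGCGC, ATGCGC, GCGCAC and AGAGCG on one side, and ATGCTC and ACGGAT on the other.

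Ribosomal protein genes stood out among the 23 gene lists fixed beforehand. Of the 250 regions, 8 (3.2%) lay within 1000 bp of the start site of a cytosolic ribosomal protein gene, against 0.198% of the background, a ratio of 16.2 (Fisher's exact test, adjusted p = 1.37e-06). Genes of the large subunit gave 6 of them, rpl-3, rpl-20, rpl-15, rpl-35 (113), rpl-12 (94.9) and rpl-1 (91.3), and genes of the small subunit gave rps-12 (84.6) and rps-1 (69.8). The share also passed in each replicate's own list, with 3 of 21 regions in replicate 1 (ratio 75.8, Fisher's exact test, adjusted p = 0.000205) and 3 of 26 in replicate 2 (ratio 51.8, Fisher's exact test, adjusted p = 0.000656). The size of the ratio thus depended on the list. Translation factors had 3 regions, at eif-2Bgamma (78.4), eif-3.B (77.2) and iff-2 (73.3), a ratio of 10.1 (Fisher's exact test, adjusted p = 0.0240). That call was lost in the conservative list, which held none of the 3. It was also lost with windows of 500 bp or 2000 bp (ratio 7.50 and 5.59, Fisher's exact test, adjusted p = 0.582 and 0.0806). The respiratory chain had 2 regions, at atp-1 and at the cytochrome oxidase gene cox-5A (84.9), and did not pass (ratio 8.59, Fisher's exact test, adjusted p = 0.109). It passed among the 125 regions of highest signal (ratio 17.2, Fisher's exact test, adjusted p = 0.0367) and with a window of 500 bp (ratio 20.9, Fisher's exact test, adjusted p = 0.0260).

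Genes of the BAG neurons were represented in the main list by ets-5 alone. The BAG list had 2 regions, both at ets-5 (ratio 21.9, Fisher's exact test, adjusted p = 0.0240), and the list of ETS-domain genes had those 2 and 1 at ets-9 (76.0; ratio 60.3, Fisher's exact test, adjusted p = 0.000281). Both calls rest on the gene that the transgene carries. Without the ets-5 interval the BAG list had 0 regions and the ETS list was left with ets-9 (ratio 25.2, Fisher's exact test, adjusted p = 0.234). Both calls were also lost in the conservative list, with 1 of 177 regions each (BAG ratio 14, adjusted p = 0.405; ETS ratio 25.8, adjusted p = 0.301; Fisher's exact test). In the replicates' own lists, with 1 region each, neither passed (Fisher's exact test, adjusted p = 0.0666 for BAG and 0.0534 for ETS in replicate 1, 0.0858 and 0.0645 in replicate 2). The ratios there were higher than in the main list, 117 for BAG and 224 for ETS in replicate 1, and 91.1 and 187 in replicate 2. Against random positions the BAG list did not pass either (ratio 13.3, Fisher's exact test, adjusted p = 0.0720). The closest to the threshold among other BAG genes was gcy-33, a soluble guanylyl cyclase gene of oxygen sensing (V:12001958-12002267, signal 73.9), at rank 448 of the ranked list with a global irreproducible discovery rate of 0.0194 in the authors' deposited table. The best regions of egl-46, flp-10, egl-13 and tax-4 ranked 10359, 12747, 13317 and 14011. Those of flp-17, flp-13, gcy-31, gcy-9 (a receptor guanylyl cyclase gene of carbon dioxide sensing) and tax-2 ranked 31683, 35321, 37022, 57597 and 100190. No ranked region lay within 1000 bp of a start site of flp-19. The chromatin came from whole larvae, so these ranks do not show whether the genes are occupied in the BAG neurons themselves.

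Other tissue and process lists had few or no regions and none passed. Single regions lay at ehs-1 (88.0) among pan-neuronal genes and at dnj-19 (81.9) in the chaperone list, which does not hold the HSP70 genes F44E5.4 and F44E5.5. There were 2 at nuclear receptor genes, nhr-47 (81.9) and nhr-277 (76.8), and 2 at cuticle collagen genes, col-108 (81.9) and col-103 (77.8). The regions at dnj-19 and nhr-47 are the same region. The other 14 lists had 0 of 250 regions: serotonergic genes, neuropeptides, guanylyl cyclases, ceh homeobox genes, mitochondrial ribosome, proteasome, spliceosome, vacuolar ATPase, histones, muscle, intestine, germline, hypodermis and ciliated neurons. A count of 0 allows a share of up to about 1.2%, taken as 3 of 250 and not from the exact intervals used elsewhere. The background shares of these lists were lower than that, at most 0.316% (neuropeptides), so the counts of 0 do not show depletion. On simulated data, moving 3 regions beside ribosomal protein genes was called in 43 of 100 draws and moving 8 in 100 of 100. A group of 3 regions at ribosomal protein genes would therefore often be missed at this list size. Other lists, whose background shares differ, were not simulated.

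Short noncoding RNA genes also lay near passing regions. Small nuclear RNA genes were within 500 bp of 6 regions (2.4% against 0.12%, ratio 20, Fisher's exact test, adjusted p = 4.24e-06). Named after their values were seen, these included 3 regions at genes of the SL2 spliced leader RNAs, sls-2.1 (102) and sls-2.2 with sls-2.3 (91.8 and 35.6), and regions at sup-39 (78.4) and sup-6 (25.9), which encode U1 RNAs. The sixth lay at T08G5.11 (82.2). The region at sup-39 is the same region as that counted at eif-2Bgamma among translation factors. The regions of signal 91.8 and 35.6 overlap each other, and with overlapping regions merged 5 remained (ratio 17.6, Fisher's exact test, adjusted p = 6.35e-05). Transfer RNA genes had 5 regions (2.0% against 0.599%, ratio 3.34) and small nucleolar RNA genes 4 (1.6% against 0.419%, ratio 3.82), each with an adjusted p of 0.0368 (Fisher's exact test). The small nucleolar RNA regions include that counted at rps-12 among ribosomal protein genes. The transfer RNA regions include 1 near ets-5, and their call was lost without the ets-5 interval (ratio 2.82, Fisher's exact test, adjusted p = 0.0932) and at 200 bp (ratio 3.82, Fisher's exact test, adjusted p = 0.0760). Pseudogenes had 11 (4.4% against 5.03%, Fisher's exact test, adjusted p = 0.965) and ribosomal RNA genes 0. The calls depended on the list: 3 of 5 gene types passed in the main list, 1 in the conservative list and 1 in replicate 2, while none passed in replicate 1 alone or among the 125 regions of highest signal. In the conservative list the ratio fell to 1.88 for transfer RNA genes (2 of 177 regions, Fisher's exact test, adjusted p = 0.723) and to 1.35 for small nucleolar RNA genes (1 of 177, adjusted p = 0.760). Among the 125 regions of highest signal, which hold fewer regions near each type, the ratios were 13.3 for small nuclear RNA genes (Fisher's exact test, adjusted p = 0.0516), 4.01 for transfer RNA genes (adjusted p = 0.1) and 3.82 for small nucleolar RNA genes (adjusted p = 0.163).

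The ets-5 gene (X:5076635-5084526, minus strand) stood in a dense stretch of passing regions. Within 20 kb on each side of it lay 13 regions of the main list, 5.2% of the list and 25.5% of its 51 regions on the X chromosome. In 10000 random windows of the same length on X, the mean was 0.101 and the highest count 2. Over all chromosomes, the next densest stretches of that length held 6 main regions each, chosen after their values were seen: from pro-1 over mnk-1 to cdc-48.1 (II:10542778-10563743) and at the Y17D7C genes Y17D7C.1, Y17D7C.2 and Y17D7C.6 (V:18705558-18723245). The 13 regions ran from 5071994 to 5102955. They lay at clc-7 (112 and 122), in the calmodulin-like gene cal-5 (74.7, 83.5 and 88.3), in an intron of ets-5 (80.3), around the ets-5 start site (128, 91.0 and 97.2), in pnk-4 (68.4), in acn-1 (80.6) and at vit-2, a yolk protein gene (74.8 and 103). The 51 ranked regions of the window outside the main list had a median signal of 36.5, where the medians of the random windows, taken over all their ranked regions, had a median of 23.2 and a 95th percentile of 27.9. The strain carries, besides its own ets-5 locus, a transgenic fosmid with ets-5. Its number of copies and the fosmid's ends are not given in the sources used here, and the window was set without them.

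**Figure D2:**
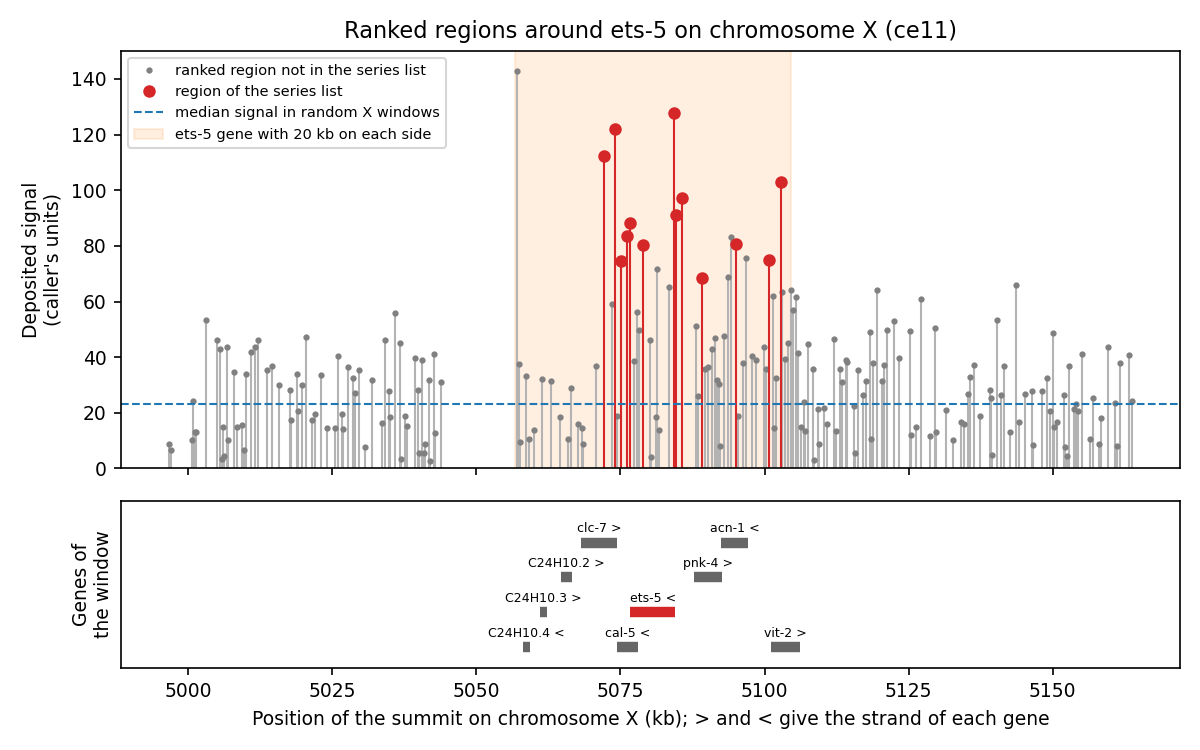
Deposited signal (vertical axis, the caller's units) of each ranked region by the position of its summit on chromosome X (horizontal axis, kb), with the genes of the window and their strands underneath; red marks the regions of the main list, grey the other ranked regions, shading the gene with 20 kb on each side, and the dashed line the median signal of random windows on X. The 13 regions of the main list lie between 5071994 and 5102955.

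Chromosomes were represented in the main list in proportion to the background. No chromosome of 6 differed after adjustment (lowest adjusted p = 0.782), and 0 of 6 had an unadjusted p under 0.05 (Fisher's exact test). The X chromosome held 51 of 250 regions, 20.4% against 17.3%. Without the regions of the ets-5 interval its ratio to the background fell from 1.18 to 0.929.

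Regions of high signal overlapped between the replicates more often than chance. Of the 100 regions of highest signal in replicate 1, 42 overlapped one of the 100 in replicate 2, where 0.0287 would be found by chance from the covered length, and at 500 regions the overlap was 107 against 0.722. Of the 42, 20 overlapped regions that the main list omits, nearly all of them repeated sequence, and of the 107, 34. The own lists of 21 and 26 regions shared 5. The list of replicate 1 overlapped 21 of the 250 main regions, 8.4% (interval 5.27% to 12.6%), and that of replicate 2 overlapped 25, 10% (interval 6.58% to 14.4%). The size of the own lists limits these shares, since 20 of the 21 regions of replicate 1 and 24 of the 26 of replicate 2 overlapped the main list. Across the 123697 regions ranked between the replicates, which are not independent of each other, the signals had a Spearman correlation of 0.229 and a Pearson correlation of 0.340. Among the 1000 regions of highest signal the Spearman correlation was -0.275 and the Pearson correlation 0.820, against 0.0809 on log2 signal. The ranked regions include 41 at the threshold that the conservative list omits, with signals up to 1728. Neither of these sets of correlations was computed without them. For the 248 main regions in that ranked list the Spearman correlation was -0.0679 and the Pearson correlation 0.211. Choosing regions by a signal that combines both replicates can itself lower a correlation between them, and no value without that effect was computed, so these values do not show that the order differed.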

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

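The tests of extra fosmid copies and of occupancy at ets-5 alone, the test of constitutive genes in general, the share of repeated sequence and the use of the odds ratio's lower bound at ribosomal genes were chosen only after the results were seen.

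Regions that the main list omits carried the highest signals of the series. The ranked list behind it held 299 regions at a global IDR of 0.01 or less, and 49 of them (16.4%) are not in the main list. Their median signal was 125 and the highest 1728.43 (X:15810994-15811178), against a highest signal of 252 in the main list, and they made up 19 of the 25 highest signals. In 48 of the 49, 98.0% (exact 95% interval 89.1% to 99.9%), at least 50% of the 31-base words occur more than once in the genome, against 19 of 250 main regions, 7.6% (Fisher's exact test, two-sided, p = 1.08e-38). Beyond 2 kb of a start site lay 85.7% of them. Of the regions of the replicates' ranked lists at this IDR, 36 of 57 (replicate 1) and 18 of 44 (replicate 2) are likewise not in the replicates' own lists.

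The gathering of 13 main regions around ets-5 has a technical candidate explanation. If the tagged protein sat at the ets-5 gene alone, regions should stop near it, but 6 lay more than 2 kb outside the gene, at clc-7, acn-1, vit-2 and pnk-4, which argues against that explanation. Additional copies of the fosmid may raise signal in the interval: the ranked regions of the window outside the main list had a median signal of 36.5, above 27.9, the 95th percentile of the medians of random windows. That median pools an uneven window. At its left edge lay 1 of the omitted regions (X:5056800-5057109), with a signal of 143, the highest of the window. From 5057414 to 5070805, between it and the first main region, the highest signal was 37.5. Further right, regions outside the main list reached 83.4. The pooled median therefore does not show where a raised stretch would begin or end. Binding within the interval on top of added copies stays open, since signal from the transgene and from the native locus was not separated. Apart from occupancy at ets-5 alone, no biological explanation was tested, because the design has 1 group.

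The regions at ribosomal protein genes were weighed against 2 technical explanations. GC content and promoter position alone are argued against, since the ratio was still 5.33 against the background matched on both (8 of 250 against 30 of 4993, Fisher's exact test, p = 0.000336), with an odds ratio between 2.14 and 12.4, after 16.2 (7.03 to 33.8) unmatched. Promoters of constitutive genes in general stay open as an explanation: 6 other such lists combined (translation factors, respiratory chain, proteasome, spliceosome, mitochondrial ribosome and vacuolar ATPase) had a ratio of 3.40 (5 of 250, odds ratio 1.11 to 8.19, Fisher's exact test, p = 0.0172), although against the matched background the ratio of 2.5 did not pass (Fisher's exact test, p = 0.0612). Those 5 regions lay at translation factors (3) and the respiratory chain (2), with 0 in each of the other 4 lists. While 0 of the 8 ribosomal regions hold CCGGAA, its share in the main list is only 10%. The count of 0 therefore does not set them apart. No biological explanation was tested, and a control precipitation was not analysed here.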

How the results depend on the processing

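No paired analysis was possible because the design has only 1 group. Of 208 alternatives, 147 kept direction and side of the threshold or a count within 1.5 times its main value, which does not say that the same lists or types passed. Of the others, 19 lost the call, 2 gained it, 22 reversed and 18 moved a count or value, and the cause was not tested. Settings without the ets-5 interval, with the omitted regions, with overlapping regions merged, with regions beyond promoters only, with an IDR of 0.005 and with main regions in the replicate comparison were chosen after seeing the data. GC content and the ribosomal list passed in all their alternatives, 8 and 11, and the planned IDR of 0.01 equals the authors' threshold and moved nothing. The promoter ratio ran from 1.2 at 1000 bp to 1.83 at 250 bp, and with a replicate left out from 1.40 (Fisher's exact test, p = 0.308, without replicate 2, where only 21 regions remain) to 1.77 without replicate 1. The CCGGAA ratio of 1.09 turned to 0.958 in the 125 regions of highest signal, 0.910 with the omitted regions, 0.944 against the matched background, 0.933 for GGAA and 0.662 for CCGGAAGT; without a replicate it ran from 1.05 to 1.21. The 311 words that passed became 124 (conservative list), 108 (highest signal), 570 (random positions), 204 (50 bp) and 8 (matched), and 1 to 34 without a replicate. With the omitted regions, 113 words were more and 239 less frequent, against 171 more and 140 less in the main list, so the balance turned. The 4 gene lists that passed became 1 in the conservative list, 1 with either replicate left out and 2 without the ets-5 interval. Ratios reversed to 0 for translation factors (conservative list, highest signal, either replicate left out), chaperones (highest signal, either replicate left out) the BAG list (without the ets-5 interval), the respiratory chain (without replicate 1), transfer and small nuclear RNA genes (without replicate 2) and small nucleolar RNA genes (either replicate left out), and that of neuropeptides from 0 to 2.20 at 2000 bp. With replicate 1 left out the ratios were 6.21 for transfer RNA genes (1 region) and 83.3 for small nuclear RNA genes (3 regions, including an overlapping pair at sls-2.4). With replicate 2 left out the ratio was 51.0 for the respiratory chain (1 region). The 3 noncoding gene types became 1 in the conservative list, 0 among the highest signals, and 0 to 1 without a replicate. The X ratio reversed to 0.929 without the ets-5 interval. The signal ratio by CCGGAA reversed to 1.00 at 50 bp and that by promoter to 0.992 at 1000 bp. An IDR of 0.005 left 114 regions. The Spearman correlation moved to -0.275 in the 1000 highest signals and -0.0679 in main regions, a choice of regions by combined signal that can itself lower it. Read depth, being unknown, limits what can be said about regions that did not pass.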

Other observations

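The test of gene lists over the whole ranked list and the shares by rank were chosen only after the results were seen.

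Over the whole ranked list, passing regions included, 2 of 23 gene lists ranked high. For each gene the highest signal of a region within 1000 bp of its start site was taken. In a random-list test, a list's median was set against 10000 random lists matched on the number of regions. Their values were drawn with replacement. GC content and distance to the start site, which also differ along the ranks, were not matched. Cytosolic ribosomal genes had a median of 50.8 against 37.5 (permutation test over random lists, adjusted p = 0.0046) and splicing factors 46.6 against 37.6 (adjusted p = 0.0046), the latter led by snr-1, a core protein of the splicing particles (81.4), prp-19 (69.5), rsp-3 (69.4) and lsm-6 (66.5). In the same permutation test, translation factors (adjusted p = 0.0767), respiratory chain, mitochondrial ribosome and cuticle collagen genes (each 0.0874) did not pass, and 0 lists ranked low. The BAG list had a median of 43.4, at percentile 85.7 of random lists (permutation test, adjusted p = 0.423), and without ets-5 a median of 38.8, at percentile 60.3 (p = 0.795). By permutation, neuropeptide genes (adjusted p = 0.618) and ciliated neuron genes (adjusted p = 0.689) lay inside the range of random lists, although single members had high ranks, such as the neuropeptide gene nlp-68 (rank 531) and the ciliated neuron gene che-12 (rank 452).

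The share of regions with CCGGAA was lower at the low ranks of the list, as was GC content. With exact 95% intervals, it was 10% (6.58% to 14.4%) in ranks 1 to 250, 11.3% (9.15% to 13.8%) in ranks 251 to 1000 and 11.1% (10.1% to 12.1%) in the following ranks to 5000. It was 10.3% (9.79% to 10.8%) in ranks 5001 to 20000, 9.43% (9.14% to 9.72%) in ranks 20001 to 60000 and 8.65% (8.44% to 8.87%) beyond. Mean GC content fell over the same ranks from 45.3% to 37.0%, and the promoter share from 33.6% to 23.3%.

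In the background regions CCGGAA lay at the summit more often than in the flanks, in 5941 regions against 5426 (exact sign test, p = 1.42e-06), and 2 explanations were tested. Summits in annotated promoters are argued against as the only source of this pattern. Beyond 1000 bp of an annotated start site, 3573 regions had more at the centre and 3250 more in the flanks, a ratio of 1.10 (exact sign test, p = 9.66e-05). Promoters without an annotated start site were not covered. Both sign tests treat regions as independent, but some neighbouring summits lie about 200 bp apart. The same word can then be counted for more than 1 region, so these p-values may be too small. Base composition at summits could account for the pattern: the central to flank ratio of 1.11 lay at percentile 52.2 of the 90 words with the same bases, whose median was 1.11 and whose highest, GGACAC, reached 1.22. Centring of this word was thus no stronger than is usual for words with its base content. Words that overlap CCGGAA are among the 90, such as ACCGGA (1.17, rank 5), CGGAAC (1.16, rank 11) and AACCGG (1.11, rank 41). The comparison therefore does not exclude ETS binding. No biological explanation was tested, because the design has 1 group.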
